A study of Mus musculus with 8 samples.

How the data were processed

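Sorted DN3 (CD44-negative, CD25-positive) and DN4 (CD44-negative, CD25-negative) thymocytes of WT and KI mice gave 8 libraries, 4 of 5′ single-cell gene expression and 4 of T cell receptor sequence, with 1 library of each kind per group. Per the labels, DN cells were enriched by magnetic depletion with antibodies against MHC class II, CD11b, CD4, CD8 and the immunoglobulin kappa chain before sorting.

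For gene expression the authors deposited raw UMI counts, a matrix of 15653 genes by 10237 cells with no normalisation, in which cells and genes had already been filtered by a rule that is not stated. Per the submitters' processing notes, Cell Ranger 3.1.0 and 6.0.1 and the mouse build mm10 were used; which version made which file is not stated. The deposited table of cells gives each cell's library, a cluster number from 0 to 9 and a cell cycle phase, with no method stated for either. For the receptor libraries the deposited contig tables hold UMI and read counts per assembled contig, per the file headers, and the deposited clonotype tables hold the fraction of the cells with each clonotype, a share the authors computed as its cell count over the sum. The contig tables were used for all receptor results, since they keep each chain with its cell. Gene positions came from GENCODE vM21 on GRCm38, matched by symbol, because the matrix has no gene identifiers.

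No cell was removed. Cells held between 717 and 46885 UMIs. Median genes per cell were 2279 in WT DN3, 2152 in KI DN3, 2465 in WT DN4 and 2822 in KI DN4, and median shares of mitochondrial UMIs were 2.63%, 2.80%, 1.77% and 1.85%, none above 7.48%. Doublets were called per library with Scrublet in scanpy 1.11.5 and made up 0.139%, 0.152%, 1.35% and 1.71% of cells, 73 cells or 0.713% in all. They were left in, and the DN3 rates, below 0.5%, may miss doublets of like cells.

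UMIs were summed over all cells of a library and divided by the library total (CPM). In each of 4 comparisons (KI against WT within DN3 and within DN4, DN4 against DN3 within WT and within KI), genes with at least 20 CPM in either library were kept and the ratio of CPM was given with an exact Poisson interval, from the conditional binomial, at 95% confidence. These intervals, and the exact binomial (Clopper-Pearson) intervals of shares, cover counting error only and say nothing about the spread between mice. With 1 library per group no test within a stage or within a genotype could be made; an additive model of genotype and stage over the 4 libraries, which leaves 1 residual degree of freedom, was not fitted. Cells were not taken as replicates, and a gene was called apart when its ratio was at least 2-fold. Ratios against 0 UMIs used a floor of 3 counts in that library and are lower bounds.

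For 32 lists of genes fixed before the data were examined, as were the comparisons, the thresholds, the rule for naming genes and all alternatives but those by cluster and by the authors' phase calls, the median log2 ratio of the members at 20 CPM or more was set against 10000 random lists of the same size and expression. A median outside their central 95% was said to lie apart; this is a description of these libraries, not a test. The lists covered Wnt, Notch, p53, NF-κB and interferon targets, GSK3 and related kinases, the response to the pre-T cell receptor, recombinase and end-joining genes, necroptosis, the BCL2 family, cell cycle, metabolism, ribosome biogenesis, immediate early and endoplasmic reticulum stress genes, and markers of thymocyte stages and of other lineages. A list with fewer than 3 measured members got no median. This left 6 lists without one in every comparison, namely early DN2, B cell, myeloid and dendritic, erythroid, stromal and sex-linked genes. Of the sex-linked list Xist was at 747, 707, 489 and 377 CPM in WT DN3, KI DN3, WT DN4 and KI DN4.

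Genes were named by rule: in each comparison the 8 highest and 8 lowest ratios whose interval excluded 1, without receptor and immunoglobulin, ribosomal protein, mitochondrially encoded and sex-linked list genes; up to 4 members of each list that lay apart; up to 6 genes over 2-fold apart in both genotype comparisons; and Gsk3b. The groups left out of naming held genes over 2-fold apart as well: in the order KI against WT in DN3 and DN4, then DN4 against DN3 in WT and KI, 2, 1, 26 and 21 receptor or immunoglobulin genes and 3, 1, 1 and 9 ribosomal protein genes. Histone genes over 2-fold lower numbered 6, 3, 0 and 1 and those higher 0, 0, 0 and 6. Reads of histone genes, pseudogenes and near-identical copies are shared between loci, so single values of these genes are uncertain.

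Deposited clusters were named from the marker lists where at least 3 markers of a class were raised and the leading genes did not go against the name, and otherwise kept their number. Cluster 5 had the markers of NK, innate lymphoid and NKT cells but kept its number because most of its cells had αβ receptor chains. Clusters 0 and 1 separate by library and were only used together. Cluster 3 is led in part by Ccnb1ip1, itself 3.85-fold apart between KI and WT DN4, so its share was not compared alone. Phase was called with the scanpy score of the S and G2/M lists after normalising each cell to 10000 UMIs, once as deposited and once after thinning each cell to 2500 UMIs, which left out 76, 90, 78 and 187 cells. Calls without thinning were the same as the authors' in 97.4% to 98.2% of cells.

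Productive β (TRB) and α (TRA) chains were counted once per cell and chain: 644, 797, 966 and 1761 TRB and 1, 2, 359 and 395 TRA chains in WT DN3, KI DN3, WT DN4 and KI DN4. Of 608, 751, 930 and 1658 cells with a contig, 597, 728, 909 and 1616 were in the expression matrix of the same group. Of full-length TRB contigs 15.5%, 17.8%, 18.1% and 18.6% were nonproductive. Segment usage was compared by the total variation distance in percent, beside the range that counting error alone gave in 1000 draws of both libraries from their pooled usage. Segments with at least 20 chains were checked for intervals that do not overlap. Diversity was the number of distinct chains (V, J and CDR3 nucleotide sequence) and the Shannon entropy in 1000 subsamples of the chain number of the smallest library, for TRA only where a library held at least 100 chains. TRBV10 lies outside the fixed parts of the locus and made up 4.97%, 5.52%, 6.21% and 5.05% of chains.

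The steps were tested on simulated data built from the summed counts, with 5703, 5420, 5711 and 5508 genes in the 4 comparisons in the order above. In each comparison 50 of 50 genes seeded at 2.5-, 4- and 8-fold were called and 0 of 50 at 1.5-fold, no unchanged gene was called, and intervals held the true ratio in 95.4%, 94.6%, 95.3% and 95.6% of genes. Of 200 unchanged lists of 15 genes 5.0%, 4.5%, 1.5% and 4.5% lay apart. These were random genes with independently drawn counts. The shares therefore do not show how often lists of genes that vary together would lie apart. With no usage moved, TRBV distances passed the counting range in 4.5% of 200 runs in DN3 and 3.0% in DN4. The simulation has no spread between mice.

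Alternatives were TMM scaling in edgeR 4.0.16 (factors 1.03, 1.02, 1.02 and 0.939), a filter of 5 CPM or none, cells under 5% mitochondrial UMIs, clusters 2, 5 and 7 left out (the γδ T-like cluster, cluster 5, and a cluster that is cycling-like by its markers but also holds 4 markers of the NK, innate lymphoid and NKT list over 2-fold), each cell thinned to 2500 UMIs, doublets left out, contigs of at least 3 UMIs, each clonotype once, cells in the expression matrix only, cells with 1 productive chain, and clonotypes by CDR3 amino acids. Chosen after the data were seen were restrictions to clusters 0 and 1 in DN3, to clusters 3 and 4 in DN4 and to cells inside or outside cluster 5, and the authors' phase calls. TMM moved the median log2 ratio of all genes by 0.01, 0.11, 0.02 and 0.12 in the 4 comparisons. For explanations of patterns, processed pseudogenes were sought with blastn 2.17.0 at 95% identity over 100 nt, and cells were compared by their 30 nearest neighbours on 30 principal components of 2000 variable genes in scikit-learn 1.9.0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and matplotlib 3.10.9 were used. Deposited clonotype tables were not used further, since clonotypes were counted per chain.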

Results

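Double-negative (DN) thymocytes, the immature thymus cells that carry neither CD4 nor CD8, were profiled by 5′ single-cell RNA sequencing and T cell receptor sequencing. They came from wild-type (WT) C57BL/6J mice and from knock-in (KI) mice in which the serine of GSK3β named in the title was replaced by alanine. GSK3β is a kinase of many pathways, Wnt signalling among them, and the title of the series asks about the range of T cell receptor β and α chains. DN3 cells (CD25-positive), the stage at which the β chain gene is rearranged, and DN4 cells (CD25-negative), the stage after it, were sorted from each genotype. Each of the 4 groups had 1 expression library and 1 receptor library, so no group has a replicate and no test within a stage or within a genotype was possible. All intervals given are 95% intervals of counting error only. The expression libraries held 2885 WT DN3, 3298 KI DN3, 1477 WT DN4 and 2577 KI DN4 cells, with medians of 5927, 5495, 7121 and 9345 unique molecular identifiers (UMIs) per cell. Summed over cells, the libraries held 22652454, 25525613, 16411164 and 30402236 UMIs.

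Gsk3b, the gene that carries the replaced serine (GRCm38 chromosome 16, 38089001 to 38246084), was read at 107 counts scaled to the library total (CPM) in WT DN3, 90.6 in KI DN3, 93.8 in WT DN4 and 74.2 in KI DN4. The log2 ratio of KI over WT was −0.24 (interval −0.32 to −0.15) in DN3 and −0.34 (−0.43 to −0.24) in DN4. The ratio of DN4 over DN3 was −0.19 in WT and −0.29 in KI. The knock-in alters the protein sequence, so these levels say nothing about kinase activity.

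The deposited clusters split the sorted cells into a few kinds. Clusters 0 and 1 carried Il2ra, which encodes CD25, at 639 and 660 CPM and were taken as pre-selection DN3-like cells. They held 78.2% of WT DN3 cells (exact binomial interval 76.6 to 79.7) and 74.9% of KI DN3 cells (73.3 to 76.3). These clusters separated the genotypes: cluster 0 held 109 WT and 2415 KI DN3 cells, and cluster 1 held 2146 and 54, so only their sum was compared. Clusters 3 and 4, led by Cd8b1, the CD8 β chain gene, by the replication genes Hells and Cdc6, and by the mitotic genes Aurkb and Plk1, held 10.7% of WT DN3 cells (9.61 to 11.9) and 14.7% of KI DN3 cells (13.5 to 15.96). In DN4 they held 33.4% of WT cells (30.97 to 35.8) and 45.0% of KI cells (43.1 to 47.0); with clusters 2, 5 and 7 left out these were 92.0% (89.3 to 94.1) and 96.8% (95.7 to 97.7). Within this pair, the cycling-like cluster 4 alone held 7.38% of WT DN3, 10.5% of KI DN3, 17.0% of WT DN4 and 15.3% of KI DN4 cells. With clusters 2, 5 and 7 left out it held 46.8% of WT DN4 and 32.8% of KI DN4 cells. The caution on comparing cluster 3 alone holds for this share too, since cluster 3 made up most of the rest.

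Much of the DN4 sort belonged to other kinds of T cell. Cluster 2, led by Myo6, the γδ receptor segment Trdv5 and the transcription factor gene Maf, was γδ T-like: its Trdc, the δ chain constant gene, reached 526 CPM against 28.4 in cluster 5. It held 40.3% of WT DN4 cells (37.8 to 42.8) and 37.9% of KI DN4 cells (36.0 to 39.8), but 0 of 2885 WT DN3 cells, which by a floor of 3 counts allows a share of up to 0.104% (exact binomial upper limit 0.128%), and 2 of 3298 KI DN3 cells. The protocol names no antibody against the γδ receptor. Cluster 5, led by the claudin gene Cldn10, the chemokine genes Ccl5 and Xcl1 and the inhibitory receptor gene Tigit, held 7 markers of the list for NK, innate lymphoid and NKT cells at over 2-fold their level elsewhere. Most of its cells carried productive α and β receptor chains, which NK and innate lymphoid cells lack, so it was left without a name. It made up 21.9% of WT DN4 cells (19.8 to 24.1) and 12.7% of KI DN4 cells (11.5 to 14.1), with 0 cells in DN3. The cycling-like cluster 7 held 1.49% of WT and 2.91% of KI DN4 cells. Cluster 6, led by Ung, Shmt1 and E2f1, held 8.42% of WT and 8.79% of KI DN3 cells and was left without a name, as were the small clusters 8 and 9.

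**Figure D1:**
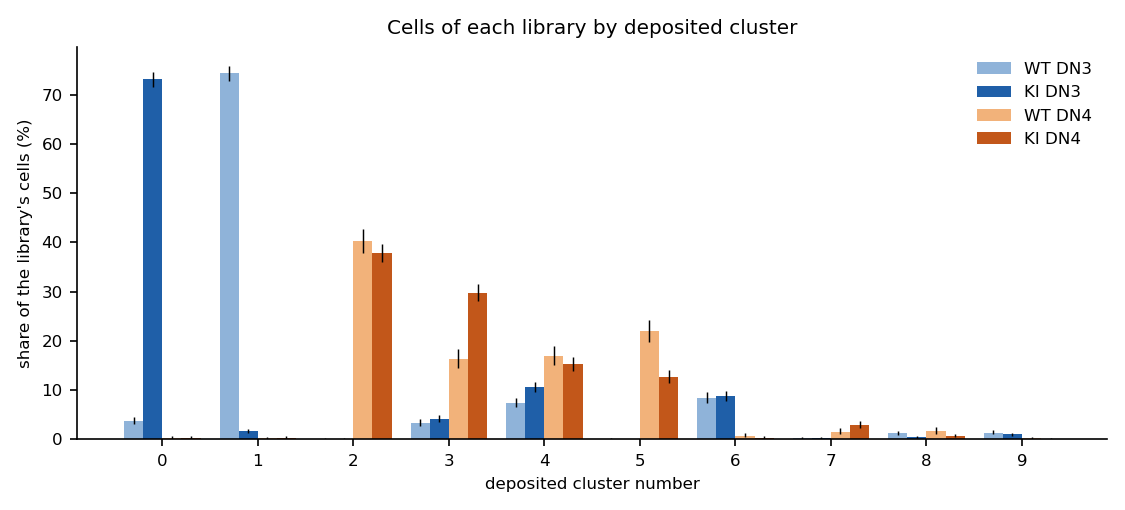
Bars give the share of each library's cells (%) in each deposited cluster, 0 to 9, for the 4 expression libraries, and lines give 95% exact binomial intervals. Cluster 5 held 21.9% of WT DN4 and 12.7% of KI DN4 cells, and clusters 0 and 1 split the DN3 cells by genotype.

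Between KI and WT DN3 cells, the genes furthest apart were much lower in KI. Mid1, a ubiquitin ligase gene at the boundary of the X chromosome's pseudoautosomal region, was at 36.3 CPM in WT and 0.470 in KI, 77.2-fold lower (log2 ratio −6.27, −7.23 to −5.46). Cd96, a receptor gene of T and NK cells, was at 64.3 and 2.43 CPM (−4.73, −5.12 to −4.36). Arhgap31 was at 25.3 and 1.80 CPM (−3.81), and Gm47283, annotated in the pseudoautosomal end of chromosome Y, at 42.5 and 3.68 (−3.53). Apobec3, a cytidine deaminase gene that restricts retroviruses, was at 191 CPM in WT and 40.3 in KI (−2.24, −2.34 to −2.14). The prostaglandin synthase gene Ptgs2 (−1.75) and the histone genes Hist1h2ac (−1.72) and Hist1h3e (−1.71) came next, and 6 of the genes lower in KI by at least 2-fold were histone genes.

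On the other side, Cd200, which encodes a surface ligand that restrains immune cells, was at 10.8 CPM in WT DN3 and 36.0 in KI DN3 (1.74, 1.54 to 1.95). Dynlt1f, a dynein light chain gene, had a log2 ratio of 1.36, Cycs, the cytochrome c gene, 1.19 (1.05 to 1.35), and Nme1, a nucleotide kinase gene, 1.16. Ywhaq, an adaptor of kinase signalling, was at 1.15, the histone deacetylase gene Hdac1 at 1.07 and the Golgi gene Sys1 at 1.03. Gm10036, annotated as a processed pseudogene with 5 near-identical copies, was at 0.93. Of these, Cycs, Nme1, Ywhaq, Hdac1 and Sys1 were lower in KI in DN4. In all, 40 of 5797 genes with at least 20 CPM in either library were 2-fold or more apart, 8 higher and 32 lower in KI. Of the 40, 26 were also among the 37 that passed in clusters 0 and 1 alone.

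Proliferation genes were higher in KI DN3 cells. Of 38 measured S phase genes, 30 had intervals above 0 and 1 below (median log2 ratio 0.20), with Clspn, a replication checkpoint gene, at 0.86 and the DNA polymerase gene Pola1 at 0.62. Of 36 genes of the G2/M phases, 31 were higher and 1 lower (median 0.45), among them the spindle motor gene Kif11 (0.83), Cdca3 (0.70) and Nusap1 (0.69). All 10 cycling markers were higher (median 0.49), with the topoisomerase gene Top2a at 134 CPM in WT and 207 in KI (0.63), and Ube2c and the survivin gene Birc5 also at 0.63. Within clusters 0 and 1 the medians were −0.07 for S phase, −0.12 for G2/M and −0.18 for the cycling markers, all inside the range of random lists, with Top2a at −0.33 and Clspn at −0.06. Nuclear genes of oxidative phosphorylation were also higher, 13 of 17 with 2 lower (median 0.14), as in Cox5a, Cox4i1 and Ndufa4, subunits of the respiratory chain, each at 0.28; their median within clusters 0 and 1, 0.07, lay inside the random range.

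Genes of interferon response and of receptor signalling were lower in KI DN3. Of 13 interferon-response genes 11 were lower and 0 higher (median −0.45), with Irf7, the factor that amplifies the response, at 36.4 CPM in WT and 19.4 in KI (−0.90), the ubiquitin-like modifier gene Isg15 at 131 and 78.2 (−0.74), Ly6a at −0.71 and the nucleic acid sensor gene Zbp1 at −0.68. Of 12 genes of the response to the pre-T cell receptor, 10 were lower and 2 higher (median −0.31), with the immediate early factor gene Egr1 at 65.3 and 39.5 CPM (−0.72), the costimulator gene Cd28 at 108 and 72.4 (−0.57), Myb at −0.44 and the activation marker gene Cd69 at −0.43. Among 17 immediate early and stress genes 10 were lower and 5 higher (median −0.11), and Junb, an AP-1 subunit gene, was at 3192 CPM in WT and 1495 in KI (−1.09), with Fos at −0.74 and Fosb at −0.68. Within clusters 0 and 1 the interferon median was −0.35, the pre-receptor response −0.22 and the immediate early genes −0.18.

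Lineage genes of T cells were lower as well. All 4 measured genes of double-positive-like cells were lower in KI DN3 (median −0.58): the thymic homing receptor gene Ccr9 was at 186 CPM in WT and 106 in KI (−0.81), Endou at 312 and 196 (−0.67), the signalling gene Themis at −0.48 and Arpp21 at −0.20. All 5 γδ genes were lower (median −0.41), as in Trgv2, at 780 CPM in WT and 512 in KI (−0.61), and Tcrg-C1 (−0.44). Notch targets were lower in 8 of 11 and higher in 1 (median −0.14), with Hes1, a repressor gene Notch induces, at 183 and 124.5 CPM (−0.55), Bcl11b at −0.24 and Tcf7 opposite at 0.18; within clusters 0 and 1 their median was 0.01. Genes of pre-selection DN3 cells, such as Rag2 (−0.30), a subunit gene of the recombinase, and Notch3 (−0.17), were lower in 6 of 8 and higher in none (median −0.17). Those of the step from DN4 to double-positive cells were lower in 8 of 11 and higher in 1 (median −0.20). Within clusters 0 and 1 the pre-selection median, −0.01, and that of the step to double-positive cells, −0.07, lay inside the range of random lists, and at 5 CPM those of Notch targets, −0.07, and pre-selection genes, −0.11, did. These 12 of 25 lists, 4 higher and 8 lower, had medians outside the central 95% of 10000 random lists of the same size and expression, and the other 13 had medians between −0.22 and 0.10. Wnt targets were at −0.02, with 7 of 18 members measured, 3 higher and 2 lower. GSK3 and related kinases were at −0.10, with 5 of 11 measured, 0 higher and 1 lower. These medians do not speak for the members that were not measured. Recombinase genes were at −0.22, end-joining repair genes at 0.10 and necroptosis genes at −0.13. Targets of p53 were at 0.04, the BCL2 family at −0.01, ribosome biogenesis at 0.01, glycolysis at 0.05, mitochondrially encoded genes at 0.10, NF-κB targets at −0.03, endoplasmic reticulum stress at −0.07 and mature αβ T cell genes at −0.16.

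In DN4, Ccnb1ip1, a ubiquitin ligase gene of meiotic recombination, was at 15.2 CPM in WT and 58.7 in KI (log2 ratio 1.95, 1.75 to 2.14) and Cd200 at 9.93 and 26.3 (1.40). The predicted gene Gm28727 (1.06) and the ATP synthase subunit gene Atp5k, at 190 and 387 CPM (1.03), completed the 4 genes at least 2-fold higher. Sgo1, a cohesin protector gene, was at 0.91, the chromosome motor gene Kif4 at 0.81, Smim27 at 0.73 and the ribosome assembly gene Pdcd11 at 0.72. Mid1 was at 35.7 CPM in WT and 0.987 in KI (−5.18), Gm47283 at 50.8 and 2.17 (−4.55), and Plcxd2, a phospholipase-like gene 7.82 Mb from Gsk3b, at 35.0 CPM in WT (−2.81). Arhgap31 was at 34.4 and 5.20 CPM (−2.73), Cd96 at 58.3 and 9.31 (−2.65) and Apobec3 at 140.1 and 33.6 (−2.06). The claudin gene Cldn10 was at 21.3 and 7.99 CPM (−1.41) but at −0.35 within cluster 5, the cluster it leads, and the nuclear receptor gene Nr4a2 was at −1.30. Of 5592 genes, 4 were at least 2-fold higher and 33 lower; the median of all genes was −0.05, and 0.07 after scaling by trimmed means (TMM).

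Proliferation genes were higher in KI DN4 cells too. Of 41 S phase genes 34 were higher and 1 lower (median 0.21), with Pola1 at 0.63 and the chromatin remodeller gene Hells at 0.50. Of 44 G2/M genes 38 were higher and 2 lower (median 0.33), with Kif11 at 0.58 and the mitotic kinase gene Aurkb at 0.53. Of 10 cycling markers 9 were higher and 1 lower (median 0.28), and Top2a was at 245 CPM in WT and 340 in KI (0.47). Within clusters 3 and 4, whose share was larger in KI, the cycling median was 0.04 and lay inside the random range, while those of S phase, 0.06, and G2/M, 0.10, lay outside it. Respiratory chain genes were higher in 13 of 17 and lower in 3 (median 0.18), with Atp5g1, an ATP synthase subunit gene, at 0.30 and Cycs opposite at −0.87.

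Several lists of signalling, stress and survival genes were lower in KI DN4 when summed over all cells, of which clusters 3 and 4 held more in KI. Notch targets (−0.13), Wnt targets (−0.06) and GSK3 and related kinases (−0.11) lay inside the random range. Only 7 of 18 Wnt targets, 1 higher and 3 lower, and 5 of 11 of the kinases, 0 higher and 2 lower, were measured. Of 14 genes of the response to the pre-T cell receptor 13 were lower and 1 higher (median −0.41), with Egr1 at 69.6 CPM in WT and 34.2 in KI (−1.02; −0.04 within clusters 3 and 4) and Cd5, a receptor gene set by signal strength, at −0.67 (−0.11 there). Immediate early genes were lower in 12 of 16 and higher in 2 (median −0.47), with Junb at 1525 and 623 CPM (−1.29), Fos at −0.89 and the mRNA decay gene Zfp36 at −0.75. All 5 NF-κB targets were lower (median −0.47), as in its inhibitor gene Tnfaip3 (−0.70), and 11 of 13 interferon-response genes were lower with 0 higher (median −0.40), as in Usp18 (−0.62). Stress genes of the endoplasmic reticulum were lower in 6 of 11 and higher in 3 (median −0.27), with Ppp1r15a, a phosphatase subunit gene, at 240 and 128 CPM (−0.91) and the chaperone gene Hspa5 at 546 and 366 (−0.58). Of 11 p53 targets 8 were lower and 0 higher (median −0.29), with the kinase gene Plk2 at −0.71 and the p53 inhibitor gene Mdm2 at −0.48. Of 7 BCL2 family genes 4 were lower and 0 higher (median −0.33), with the survival gene Bcl2 at 84.6 and 49.5 CPM (−0.77) and the death gene Bcl2l11 at −0.72. Within clusters 3 and 4 the BCL2 family, at −0.17, and NF-κB targets, at −0.16, lay inside the random range, as they did at −0.22 and −0.19 with the cells of clusters 2, 5 and 7 left out.

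Genes of other lineages were lower in KI DN4, where cluster 5 made up a smaller share of the cells. It held 324 of 1477 cells in WT and 328 of 2577 in KI. From shares alone a loss of cluster 5 cannot be told from a gain of other clusters. Clusters 2, 5 and 7 together also weighed less in the summed UMIs of KI. The other clusters gave 10660215 of 16411164 UMIs in WT DN4 and 22889937 of 30402236 in KI DN4. Medians were also taken with clusters 2, 5 and 7 left out. No list that lay apart in KI against WT DN4 and still had a median then turned direction. The sizes of these changes are not given here for the lists below. Cluster 5 held the γδ gene Sox13 at 0.652 CPM against 134 in cluster 2, so the share of cluster 5 bears little on that gene. All 10 γδ genes were lower (median −0.54), as in the scavenger receptor gene Cd163l1 (−0.97), the factor gene Sox13 at 42.8 and 24.3 CPM (−0.82) and Maf (−0.78); within cluster 2 these were −0.65, −0.58 and −0.38. Of 5 genes of NK, innate lymphoid and NKT cells 4 were lower and 0 higher (median −0.57), with Ccl5 at −0.97 and Il2rb, an interleukin receptor gene, at 76.8 and 44.7 CPM (−0.78). Within cluster 5, Ccl5 was at 0.05 and Il2rb at 0.01. Mature αβ T cell genes were lower in 7 of 9 and higher in 0 (median −0.32), as in the egress receptor gene S1pr1 (−0.75; −0.48 within cluster 5). Double-positive-like genes were lower in 7 of 8 and higher in 0 (median −0.54), with the adhesion gene Cd2 at −0.75 (−0.37 within clusters 3 and 4), and genes of the step to double-positive cells were lower in 10 of 14 and higher in 1 (median −0.34). In DN4 16 of 26 lists, 4 higher and 12 lower, lay outside the random range, and the other 10 had medians between −0.18 and 0.14. Wnt targets were at −0.06, GSK3 and related kinases at −0.11, recombinase genes at −0.08, end-joining repair genes at 0.05, necroptosis genes at −0.18, Notch targets at −0.13, pre-selection DN3 genes at −0.13, ribosome biogenesis at 0.07, glycolysis at 0.14 and mitochondrially encoded genes at 0.10.

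**Figure D2:**
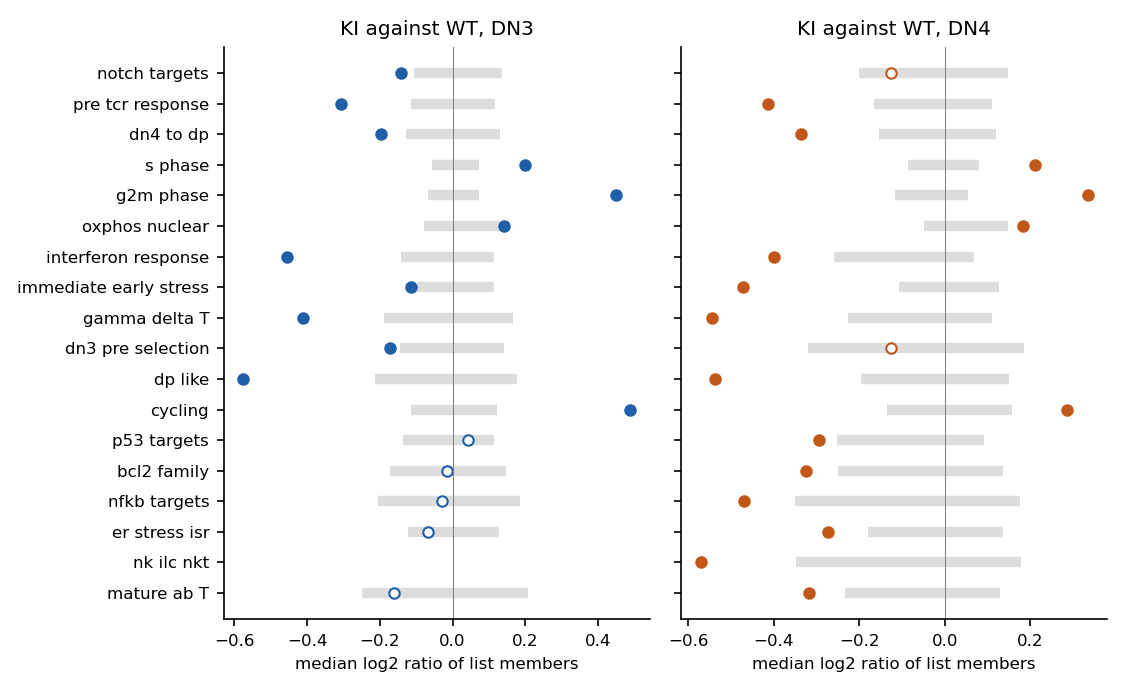
Each point is the median log2 ratio of CPM, KI over WT, of a gene list in DN3 (left) and DN4 (right); grey bars span the central 95% of random lists, and filled points lie outside it. S phase genes had medians of 0.20 and 0.21, and interferon-response genes −0.45 and −0.40.

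At both stages 11 genes were at least 2-fold apart in the same direction. Cd200 (GRCm38 chromosome 16, 45382135 to 45409053) was higher in KI. Mid1 (chromosome X, 169685199 to 170005736), Gm47283 (chromosome Y, 90784738 to 90816464), Cd96 (chromosome 16, 46035657 to 46120251), Arhgap31 (chromosome 16, 38598340 to 38713274), Apobec3 (chromosome 15, 79891659 to 79915906), Hist1h2ac, Junb, the nuclear receptor gene Nr4a3, the amino acid transporter gene Slc38a2 and the nuclear matrix gene Banp were lower; these last 3 were named after their values were seen. Atp5k was over 2-fold apart in opposite directions, lower in KI DN3 and higher in KI DN4. Across 5229 genes the log2 ratios of KI over WT in DN3 and DN4 had a Pearson correlation of 0.53, and 72.1% had the same sign; this is across genes, which are not independent replicates.

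**Figure D3:**
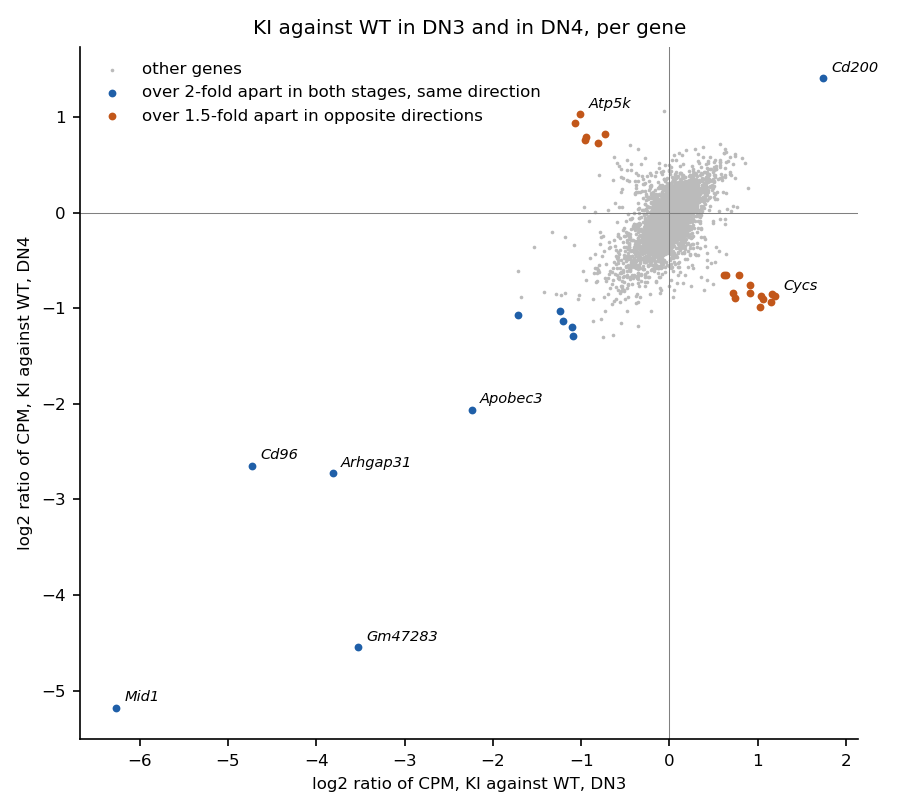
Each point is a gene, with its log2 ratio of CPM, KI over WT, in DN3 (x axis) and in DN4 (y axis); blue marks genes over 2-fold apart in the same direction at both stages, orange genes over 1.5-fold apart in opposite directions. Mid1 lies at −6.27 and −5.18, and Cd200 at 1.74 and 1.40.

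Between the stages, WT DN4 cells held far less of the genes of the DN3 stage. Il2ra, whose product CD25 defined the sort, was at 478 CPM in DN3 and 3.84 in DN4 (log2 ratio −6.96), the predicted gene Gm4632 at 635 and 2.62 (−7.92) and Cdkn1a, a cell cycle inhibitor gene, at 108 and 3.78 (−4.84). Khdc1a, with 3 UMIs in DN4, had a log2 ratio of −7.33 (−9.61 to −5.77), and Gm5111, with 0 UMIs in DN4 against 661, was at least 159.6-fold lower. The integrin gene Itgb4 (−6.04), Bst1 (−5.04) and the factor gene Spib (−4.95) were also lower. Notch3, a receptor gene of the stage, was at 60.7 and 5.30 CPM (−3.52), the Notch target Dtx1 at −3.18 and the pre-receptor gene Ptcra at 408 and 69.9 (−2.55; 0.00 within clusters 3 and 4). Notch targets were lower in 9 of 11 and higher in 2 (median −2.02), pre-selection DN3 genes lower in 8 of 8 (−2.36) and mitochondrially encoded genes lower in 12 of 13 (−0.40), as in the oxidase gene mt-Co1 (−0.60). Recombinase genes had a median of −1.19, with Rag1, the recombinase gene, at 99.6 and 31.9 CPM (−1.64; 1.34 within clusters 3 and 4) and Dntt, the nucleotide-adding enzyme gene, at −1.19.

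WT DN4 cells held more of the genes of later and of other lineages. Il2rb, with 2 UMIs in DN3, was at 76.8 CPM in DN4 (9.76, 7.91 to 12.81); Gimap3 (9.37) and Cldn10 (8.91) each had 1 UMI in DN3. Ccr8, a chemokine receptor gene, Trpm1, a channel gene, and Ccl5 had 0 UMIs in DN3 and were at least 353-fold, 221-fold and 179-fold higher. The nucleotidase gene Samhd1 (7.41) and the myosin gene Myo6 (6.86) followed. Cd8b1 was at 4.64 and 160.5 CPM (5.11; 4.14 within clusters 3 and 4), Cd2 at 5.95 and the α chain constant gene Trac at 4.31. Double-positive-like genes were higher in 5 of 8 and lower in 3 (median 2.49), those of the step to double-positive cells higher in 8 of 15 and lower in 7 (0.62), mature αβ T cell genes higher in 6 of 9 and lower in 3 (2.72), as in S1pr1 (5.42) and its regulator gene Klf2 (4.46), and NK, innate lymphoid and NKT genes higher in 4 of 5 and lower in 1 (3.09), as in Fcer1g (3.09) and Gzma (1.55). Of 10 γδ genes 5 were higher and 4 lower (0.60), with the factor gene Etv5 at 3.68, Maf at 3.06 and Tcrg-C1 at −1.77. With the cells of clusters 2, 5 and 7 left out, the medians of the mature αβ genes, −1.74, the γδ genes, −2.37, and the genes of the step to double-positive cells, −0.45, turned below 0.

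Proliferation and metabolism genes were higher in WT DN4 than in WT DN3. S phase genes were higher in 37 of 39 and lower in 1 (median 0.58), as in the nucleotide reductase gene Rrm2 (1.39), G2/M genes higher in 39 of 40 and lower in 1 (0.80), as in the cyclin gene Ccnb2 (1.31), and cycling markers higher in 10 of 10 (0.90), as in Mki67 (1.05). Glycolysis genes were higher in 10 of 13 and lower in 3 (0.35), as in Pfkp (1.32), and respiratory chain genes higher in 16 of 17 and lower in 1 (0.23). Genes of the response to the pre-T cell receptor had a median of 0.27, with Cd5 at 2.22 and the inhibitor gene Nfkbia at 1.85, and Wnt targets 0.32, with Jun opposite at −1.95; without clusters 2, 5 and 7 these medians were −0.49 and −0.13. In all 493 of 5987 genes were at least 2-fold apart, 229 higher and 264 lower in DN4, and 16 of 26 lists lay outside the random range, 12 higher and 4 lower.

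The stages of KI cells differed much as those of WT cells did. Il2ra was at 425 CPM in DN3 and 3.75 in DN4 (−6.82), Gm5111 at −7.40, Gm4632 at −7.20, Cdkn1a at −5.40, the protease inhibitor genes Ctla2a (−6.12) and Serpinb1a (−5.18), Itgb4 at −5.04 and the imprinted H19 at −4.84. Notch3 (−3.71), Dtx1 (−3.22) and Hes1 (−2.78) were lower, with medians of −1.86 for Notch targets and −2.78 for pre-selection DN3 genes, of which 7 of 7 were lower. Ccr8, with 2 UMIs in KI DN3, had a log2 ratio of 8.35 (6.49 to 11.40), Il2rb 7.35, Samhd1 6.85, Myo6 6.02, the tetraspanin gene Tspan32 6.02, Gimap4 6.01, Cd7 5.66 and Cd2 5.15. Cd8b1 was at 4.46 and Trac at 3.38. Double-positive-like genes had a median of 2.13, which was −0.30 without clusters 2, 5 and 7, mature αβ genes 2.43, which was −1.76 without them, genes of the step to double-positive cells 0.64, which was −0.30, and NK-type genes 2.33. S phase genes were higher in 40 of 41 and lower in 1 (0.57), as in Hells (1.35), G2/M genes in 43 of 44 with 1 lower (0.70) and cycling markers in 10 of 10 (0.66). The γδ genes, 3 higher and 5 lower of 8, had a median of −0.60, against 0.60 in WT; this difference was not tested, and with genes of at least 5 CPM the KI median was 0.61. In KI 450 of 5822 genes were at least 2-fold apart, 156 higher and 294 lower, and 12 of 26 lists lay outside the random range, 8 higher and 4 lower; the median of all genes was −0.07, and 0.05 after TMM scaling. Lists inside it in both genotypes were end-joining repair, p53 targets, necroptosis, the BCL2 family, ribosome biogenesis, interferon response, NF-κB targets, immediate early genes, endoplasmic reticulum stress and GSK3 and related kinases, with medians from −0.28 to 0.17 in WT and from −0.24 to 0.11 in KI. In KI those of the respiratory chain (0.24), Wnt targets (0.08), recombinase genes (−0.20) and the response to the pre-T cell receptor (−0.03) lay inside it too, mitochondrially encoded genes were at −0.38 and glycolysis at 0.26.

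Of 5707 genes measured in both genotypes, 120 were at least 2-fold higher in DN4 in both (190 in WT and 150 in KI; 4.99 for independent lists) and 225 lower (242 and 287; 12.2), with 0 in opposite directions. Across genes the stage ratios of WT and KI had a Pearson correlation of 0.87.

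**Figure D4:**
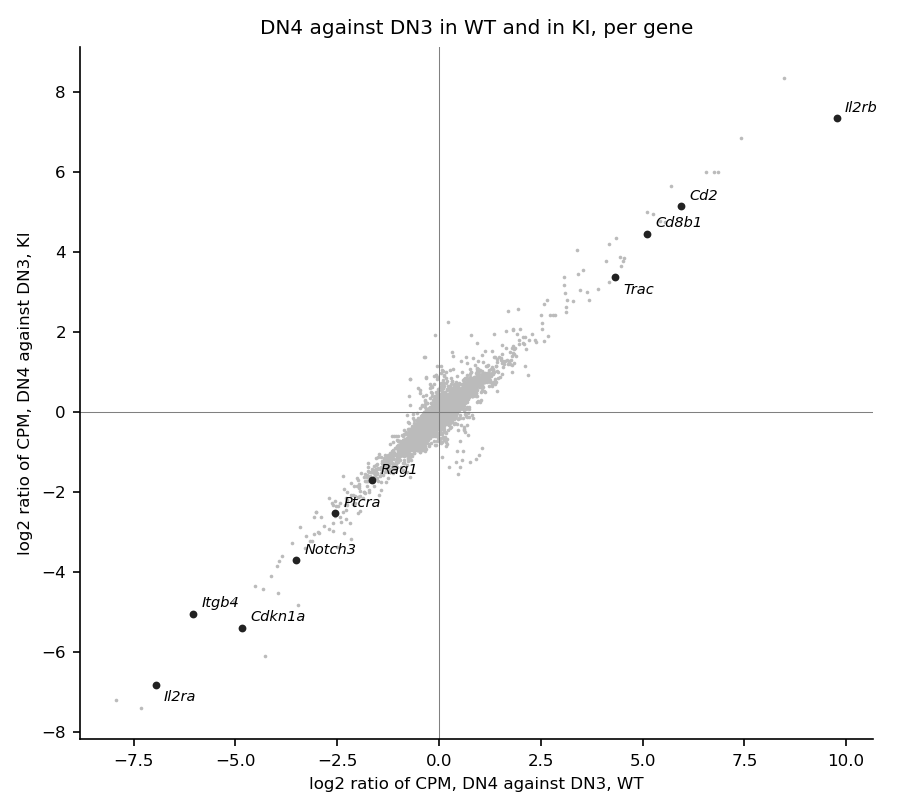
Each point is a gene, with its log2 ratio of CPM, DN4 over DN3, in WT (x axis) and KI (y axis). Il2ra lies at −6.96 and −6.82, and Il2rb at 9.76 and 7.35.

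Cells called in S or G2/M phase from equal numbers of UMIs made up 33.3% of WT DN3 (31.5 to 35.0), 37.2% of KI DN3 (35.5 to 38.9), 44.7% of WT DN4 (42.0 to 47.3) and 58.0% of KI DN4 cells (56.0 to 60.02). With clusters 2, 5 and 7 left out the DN4 shares were 94.7% in WT (92.3 to 96.5) and 97.3% in KI (96.2 to 98.1), near the ceiling of the calls, since clusters 3 and 4 make up most of the cells left. In clusters 0 and 1 of DN3 the calls were 18.2% in WT and 17.8% in KI, a level that marks the background of the calls, and in clusters 3 and 4 they ranged from 95.3% to 100%. Without thinning, clusters 0 and 1 gave 3.06% and 2.55%, and the 4 libraries 20.4%, 24.6%, 39.3% and 52.2%. Free RNA that differs between libraries was not excluded, so the calls alone do not show more dividing cells.

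A productive receptor β chain was found in 20.7% of WT DN3 cells (19.2 to 22.2), 22.1% of KI DN3 (20.7 to 23.5), 60.7% of WT DN4 (58.2 to 63.2) and 62.4% of KI DN4 cells (60.5 to 64.3). It was found in 6.87% (5.86 to 7.997) of WT and 4.78% (3.97 to 5.70) of KI cells in clusters 0 and 1 of DN3, in 71.2% and 68.3% of cluster 6, and in 85.1% and 83.7% of clusters 3 and 4. In DN4, clusters 3 and 4 had it in 95.1% of WT and 94.9% of KI cells, the γδ T-like cluster 2 in 18.7% and 18.6%. An α chain was found in 21.5% of WT DN4 (19.4 to 23.6) and 13.8% of KI DN4 cells (12.5 to 15.2); most came from cluster 5, where 83.0% and 80.8% of cells had it against 2.03% and 1.12% in clusters 3 and 4. DN3 libraries held 1 and 2 α chains and were not compared.

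Use of β chain segments, taken over each locus, did not differ detectably between KI and WT at this depth. TRBV12-1 was in 10.1% of WT and 8.03% of KI chains in DN3 and in 8.80% and 9.20% in DN4; TRBV5 was in 7.76% and 9.54%, then 5.69% and 8.06%; and TRBJ2-7 was in 14.3% and 12.7%, then 13.9% and 14.4%. The label that joins TRBV12-2 and TRBV13-2 was in 8.07% and 7.28% of DN3 chains and in 9.32% and 9.37% of DN4 chains. The distance between genotypes, the percent of chains to be moved to make usages equal, was 9.60 for TRBV in DN3 and 8.03 in DN4, inside the ranges of 6.30 to 12.4 and 4.72 to 9.56 that 1000 random draws of both libraries from their pooled usage gave. For TRBJ it was 6.86 (range 4.10 to 10.4) and 4.35 (3.07 to 7.59), and no TRBV or TRBJ segment had intervals that parted. The interval of the ratio itself excluded 1 for TRBV15 in DN3 (5.90% and 8.91%, ratio interval 1.004 to 2.30) and TRBV5 in DN4 (1.03 to 1.97); both were picked out after their values were seen, from all segments, without correction for their number. By position along the locus, TRBV1 to TRBV5 made up 22.2% of WT and 23.3% of KI chains in DN3 and 22.0% and 23.5% in DN4. TRBV12 to TRBV20 made up 60.1%, 58.2%, 59.9% and 57.1%, TRBV21 to TRBV30 7.92%, 8.66%, 8.28% and 9.54%, TRBV31, which rearranges by inversion, 4.81%, 4.27%, 3.52% and 4.88%, and TRBJ1 segments 43.2%, 44.7%, 41.2% and 41.3%, each in the order WT DN3, KI DN3, WT DN4, KI DN4. With 644, 797, 966 and 1761 chains, a simulation moved chains onto the least used TRBV segment. A shift of 5% of chains was found in 32.5% of runs in DN3 and 53.5% in DN4. One of 10% was found in 90.5% and 100%. Shifts spread over several segments were not simulated, so the shares found say nothing about those.

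**Figure D5:**
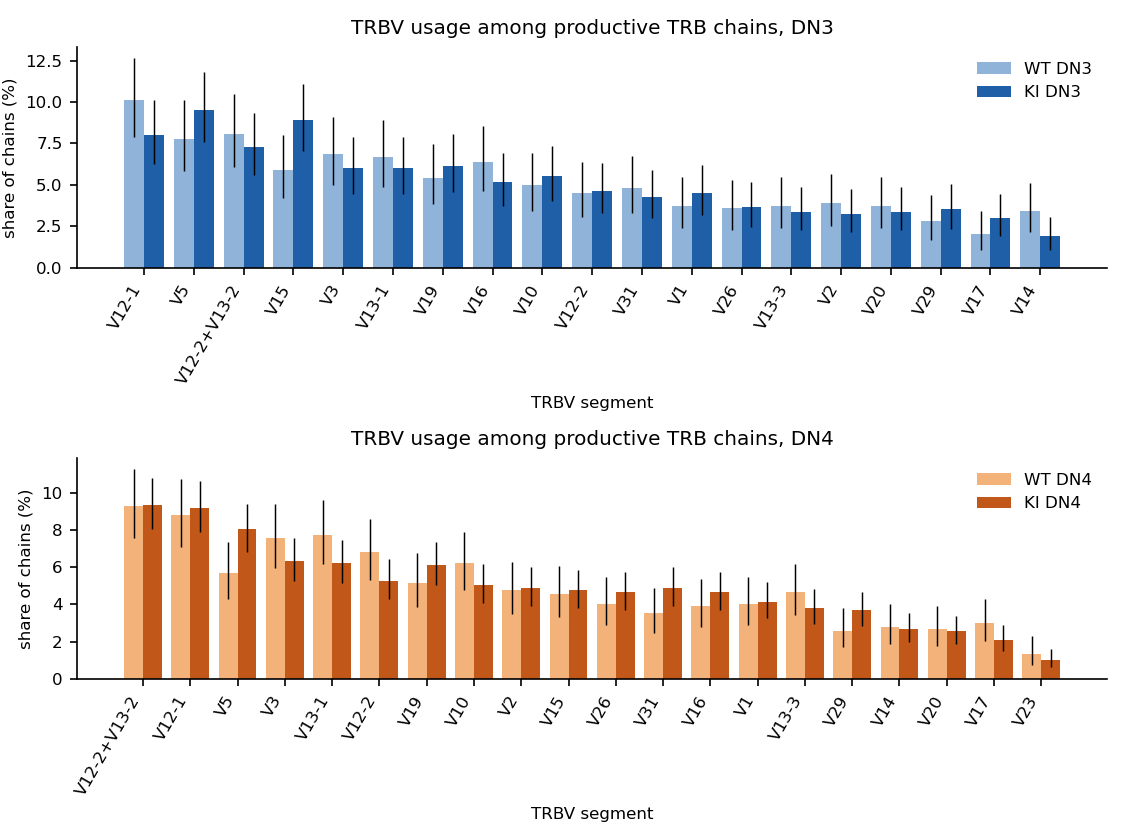
Bars give the share of productive β chains (%) that use each TRBV segment in WT and KI, in DN3 (top) and DN4 (bottom), and lines give 95% exact binomial intervals. The intervals of WT and KI overlap at every segment, as for TRBV12-1, with 10.1% and 8.03% in DN3.

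The α chains of DN4, 359 in WT and 395 in KI, gave distances of 24.8 for TRAV (range 20.01 to 28.6) and 20.1 for TRAJ (14.1 to 22.6). TRAV12-2 was in 3.90% and 3.54%, TRAJ22 in 5.85% and 8.10%, TRAJ23 in 6.13% and 4.81% and TRAJ26 in 3.06% and 7.09% of WT and KI chains, with intervals that overlapped; the ratio's own interval excluded 1 for TRAJ26 (1.12 to 5.15) and for TRAV13N-4 (1.67% in WT and 0 of 395 chains in KI), again picked out afterwards. Along the TRAJ locus, the part nearest the TRAV segments held 31.5% and 30.9%, the middle 47.1% and 47.1%, and the part furthest from them 21.4% and 22.0%. Of the α chains in cells with expression data, 85.7% of WT and 75.2% of KI chains came from cluster 5.

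Nearly every β chain sequence was seen once. At 644 chains drawn per library the number of distinct nucleotide clonotypes was 632 in WT DN3, 629.5 in KI DN3 (range 625 to 634), 634.6 in WT DN4 (630.0 to 639) and 637.6 in KI DN4 (633 to 642), with Shannon entropies of 9.29, 9.29, 9.30 and 9.31 bits against a maximum of 9.33. The largest clonotype had 3 chains, so diversity was limited by the number of cells. At 359 α chains WT DN4 had 357 distinct clonotypes and KI DN4 351.5 (350.0 to 354). The CDR3, the stretch of the chain that meets antigen, averaged 42.2 nt (SD 5.24) in WT DN3 β chains, 42.3 (5.12) in KI DN3, 42.5 (4.54) in WT DN4 and 42.5 (4.55) in KI DN4, and 40.7 (4.65) and 41.8 (4.69) in the α chains of WT and KI DN4.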

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

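Of the tests in this part, those chosen only after the result was seen were the place of the 11 genes on the chromosomes, their ratios within clusters, and the second neighbour measure.

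Genes that differed between KI and WT in opposite directions in DN3 and DN4 were looked at because the knock-in is the same at both stages; the differences between stages were not tested. As log2 ratio in DN4 minus log2 ratio in DN3, 13 genes higher in KI DN3 and lower in KI DN4 gave −2.08 (Ywhaq), −2.07 (Cycs), −2.01 (Rpl21), −2.01 (Nme1), −1.97 (Hdac1), −1.90 (Sys1), −1.76 (Akirin2), −1.66 (Erh), −1.63 (Rps7), −1.56 (Ftl1-ps1), −1.43 (Rpl36al), −1.30 (Hmga1b) and −1.26 (Trbv17). The other 6, lower in KI DN3 and higher in KI DN4, gave 1.54 (Smim27), 1.56 (mt-Atp8), 1.72 (Rpl38), 1.74 (Rps28), 2.01 (Rps29) and 2.04 (Atp5k). Opposite directions by themselves do not mean that WT DN3 and KI DN4 had like levels, but some of these genes had them. In the order WT DN3, KI DN3, WT DN4 and KI DN4, Ywhaq was at 25.4, 56.3, 50.6 and 26.5 CPM. In that order Cycs was at 22.2, 50.9, 41.4 and 22.7, and Smim27 at 41.6, 23.7, 25.2 and 41.97. For mt-Atp8 the levels were 305, 184, 185 and 328. Other genes did not pair in this way: Trbv17 was at 18.7, 28.6, 84.7 and 54.0, and Rps29 at 2401, 1143, 2260 and 4344. Why WT DN3 and KI DN4 were alike in some genes was not tested.

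A different mix of cells is argued against for these genes other than Trbv17, since 19 of 19 kept opposite directions within clusters 3 and 4 of both stages. For Trbv17, a receptor segment, the clusters cannot decide, since the share of cells that use it can differ within a cluster. TRBV17 was in 2.02% of WT and 3.01% of KI β chains in DN3, and in 3.002% and 2.10% in DN4. These shares moved in the directions of its RNA, though their intervals overlapped at both stages. A different mix of cells stays open for this gene. The 6 genes lower in KI DN3 had a median transcript length of 413.5 nt, below the lower bound of 934 nt of random sets of like expression, so a difference between library preparations in the recovery of short transcripts is a candidate explanation for them. Of the 13 genes higher in KI DN3, 61.5% had a processed pseudogene, above the 38.5% that random sets reach but below the bound of 80% set for a whole cause: Nme1, Sys1, Akirin2, Hmga1b and Trbv17 had none. Sharing of reads with copies therefore stays open for part of this set. Of the 6 genes of the other direction, Rpl38, Rps28, Rps29 and Atp5k had such copies too, and Smim27 and mt-Atp8 had none. Having a copy thus does not by itself tell the directions apart. An effect of the knock-in that turns between stages was not tested and stays open, and no label names a library batch.

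A second pattern is the 11 genes over 2-fold apart in the same direction at both stages. Of these, 9 stayed over 2-fold apart within clusters 0 and 1 of DN3 and within clusters 3 and 4 of DN4. A different mix of cells is argued against for those 9. It stays open for Junb and Nr4a3, which did not stay so in both sets of clusters. A chromosome segment from another strain carried along with the edited Gsk3b is argued against for the whole set, as 8 genes lie on other chromosomes, and is a candidate explanation for the other 3: Arhgap31, Cd200 and Cd96 lie 0.488, 7.23 and 7.91 Mb from Gsk3b, where 0.0819 genes would lie by chance and the fullest other window of 20 Mb held 2. All 38 genes within 10 Mb of Gsk3b had a mean absolute log2 ratio at percentile 99.96 of 4572 other windows (0.398 against a median of 0.169), past the bound of 95 set beforehand, but at 78.3 without those 3 genes, so this test rests on the same genes and was taken as undecided after it was seen. Plcxd2, 7.82 Mb from Gsk3b, was lower in KI as well (log2 ratio −2.81 in DN4 and −2.42 in DN3, where it was below 20 CPM and so not among the 11). A strain background away from Gsk3b, which could bear on Mid1 at the pseudoautosomal boundary and on Apobec3, and an effect of the knock-in itself were not tested and stay open.

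The third pattern is the split of pre-selection DN3-like cells into cluster 0 (2415 KI and 109 WT cells) and cluster 1 (54 KI and 2146 WT cells). Neighbour tests could not decide among its explanations: with all genes 59.2% of the 30 nearest neighbours came from the same library, and 56.0% by a second measure without scaling of genes, where 50% is equal mixing, so neither measure recovered the split and both started below the 75% that the tests needed. The values were 53.7% (thinned cells) and 56.9% (without 76 genes that differ between the libraries). By the second measure thinned cells, with all genes kept, gave 53.8%. Without those 76 genes and ribosomal protein, mitochondrial, histone and immediate early genes it gave 53.3%. Under the rule as first set these would have counted for depth and for a few genes, and the 56.3% found in cluster 5 of DN4, below the bound of 60%, against a difference in every kind of cell; the rule was altered once the start was seen, because a value that starts below the bound shows nothing by staying there. With all genes the first measure gave 71.1% in cluster 4 of DN3, and 71.9% in cluster 4 and 66.0% in cluster 3 of DN4. With thinned cells these fell to 51.5%, 51.1% and 52.9%. Thinning also cuts the signal in each cell, so these falls do not single out depth. With all genes it gave 54.0% in cluster 6 of DN3 and 55.6% in cluster 2 of DN4. For the split of clusters 0 and 1, depth per cell, a few genes, a difference between libraries and an effect of the knock-in cannot be told apart here.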

How the results depend on the processing

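Restrictions to clusters 0 and 1, to clusters 3 and 4 or by cluster 5, and the authors' phase calls, were chosen only after results were seen; the other alternatives were planned. No paired analysis was possible because no label pairs the mice of the groups, and leaving out a library was not possible with 1 per group. Another clustering resolution did not apply, since the clusters are deposited. Beyond the values below, 40 class shares without doublets, 60 receptor values and 12 gene counts stayed within their bounds. A further 306 list medians were counted as unchanged. These either kept their direction and their side of the random range, or lay inside it in the main result and changed sign. For those that changed sign, the side of the range afterwards was not checked. Another 24 medians kept their direction and moved outside that range, and 11 kept it and moved inside. For the values that follow, the cause was not tested unless it is named.

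Counts of genes 2-fold apart, in the order KI against WT in DN3 and DN4, then DN4 against DN3 in WT and KI, were 84, 115, 995 and 936 at 5 CPM and 396, 567, 1932 and 2044 without a filter, where more genes are tested at higher counting error. With clusters 2, 5 and 7 left out 24 genes (17 shared with the full set) were apart in KI against WT DN4, 874 (321 shared) between stages in WT and 766 (350 shared) in KI. With thinned cells these were 60 (27 shared), 856 (453 shared) and 799 (409 shared). Under TMM the counts were 38, 28, 488 and 438, of which 21.4% instead of 10.8% were higher in KI in DN4 and 47.0% instead of 34.7% higher in DN4 between KI stages.

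Medians that turned direction in KI against WT DN3 within clusters 0 and 1 were those of Notch targets (0.012), S phase (−0.0704), G2/M (−0.12) and cycling markers (−0.18). Between WT stages, with clusters 2, 5 and 7 left out, Wnt targets (−0.13), the pre-T cell receptor response (−0.49), the step to double-positive cells (−0.45), γδ (−2.37) and mature αβ T cell genes (−1.74) turned. Between KI stages the step to double-positive cells (−0.30), double-positive-like (−0.30) and mature αβ genes (−1.76) turned with clusters 2, 5 and 7 left out, and γδ genes (0.61) at 5 CPM.

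The TRBV distance in DN3 was 22.3 within clusters 0 and 1 (counting range 13.4 to 27.3, 162 and 121 chains), and outside cluster 5 the TRAV distance was 56.6 (36.5 to 57.1, 51 and 96 chains) and the TRAJ distance 39.6 (27.4 to 48.2); fewer chains raise the distance that counting gives. By CDR3 amino acids 95.2% of KI DN4 TRA chains were distinct. Cells in S or G2/M made up 20.4%, 24.6%, 39.3% and 52.2% of WT DN3, KI DN3, WT DN4 and KI DN4 without thinning, and 20.6%, 25.2%, 39.3% and 52.1% by the authors' calls. In simulated libraries of this depth most TRBV shifts of 10% of chains onto the least used segment were found. TRBV shifts spread over several segments, and shifts of TRBJ, TRAV and TRAJ, were not simulated. Genes below 20 CPM in both libraries entered no main count or median.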

Other observations

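No test was run for this part, which gives values alone.

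Cells of cluster 5 carried receptors of αβ T cells. A productive TRB chain was found in 89.8% of WT and 89.9% of KI DN4 cells of the cluster and a TRA chain in 83.0% and 80.8%. Trac was at 294 CPM in cluster 5 against 104 in cluster 2, Klf2, a gene of mature T cells, at 386 against 283, and Zbtb16, which encodes the factor of innate-like T cells, at 6.52 against 30.3. Ccl5, Xcl1, Tigit and Cldn10 led the cluster.

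The most frequent TRA sequence in both DN4 libraries was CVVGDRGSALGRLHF, which joins TRAV11 and TRAJ18, the segments of the invariant receptor of NKT cells. It was read in 4 WT chains with 2 nucleotide sequences and in 8 KI chains with 5. TRAV11 with TRAJ18 made up 5 of 359 WT chains (1.39%, 0.454 to 3.22) and 9 of 395 KI chains (2.28%, 1.05 to 4.28). Of these, 3 WT and 9 KI chains came from cluster 2, and 1 and 0 from cluster 5.

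Any pair of libraries shared between 0 and 1 TRB nucleotide clonotypes, and the DN4 libraries of WT and KI shared 2 TRA clonotypes. KI DN3 held 2 distinct TRA clonotypes, and each DN4 library shared 1 of them. By amino acid sequence the pairs of libraries shared between 1 and 8 TRB clonotypes.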
